A study of Mus musculus with 6 samples.

How the data were processed

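Skeletal muscle stem cells were sorted from the limb muscles of male C57BL/6 mice as cells negative for CD45, CD31 and Sca1 and positive for VCAM. They were then stained with ThiolTracker Violet at 5 uM, a dye that reports reduced glutathione (GSH), and sorted again. The 6 libraries form 3 groups of 2: young cells (4 months, all cells kept, 1 animal per library), old GSH-high cells and old GSH-low cells (23 months, 2 animals pooled per library). RNA was copied with oligo(dT) primers and read as single ends of 150 bp on a NextSeq 500, and the labels state 68 to 98 M reads per library.

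The authors' notes name Trim Galore, STAR, featureCounts from Subread, and edgeR, with the mouse build GRCm38 (mm10) and no tool versions. The authors' file gives RPKM (reads scaled to gene length in kilobases and to library size) for 12067 genes, of which 7 symbols fill 2 lines each. The values were checked for being whole read numbers divided by 1 constant per library and gene: within 0.02 reads plus a relative tolerance of 3e-07, this held for 12065 genes (99.98%) in all libraries. The constants matched library sizes scaled by TMM (trimmed mean of M values, a correction for composition) to within 0.011%. The file holds no value of 0: 230 values in 144 genes equalled 0.5 times the gene's lowest other value and were read as replaced zeros, 65 and 72 of them in the young libraries and 19 to 25 in each old library. Of the symbols, 11988 (99.3%) were found in GENCODE M21, which gave positions and gene lengths. The strand of the libraries is not stated, so that reads of overlapping genes cannot be assigned with certainty, nor can reads of near-identical genes such as Hspa1a and Hspa1b or the members of the H2 and alpha-globin families.

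Genes with RPKM of at least 1 in 2 or more libraries were kept, which left 10609 genes and removed 1458. Values were taken as log2(RPKM + 1) and fitted with limma-trend (limma 3.58.1 in R 4.3.3) as a means model of the 3 groups over all 6 libraries, with 3 residual degrees of freedom. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, over all genes tested. The added 1 shrinks fold changes of genes with low RPKM, so that fitted changes and ratios of mean RPKM differ for those genes. The plan for a table of counts was a count model. Since the file holds RPKM, the plan for normalised values, written beforehand beside it, was used. Groups, comparisons, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Recovery of reads and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

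There were 42 gene lists: 32 of pathways, complexes and cell states, and 10 of markers of other cell types. Each was tested with limma's camera at its preset correlation of 0.01, for lists with at least 5 measured members, and the p-values were adjusted over the 42 lists. Camera with a correlation estimated for each list and fry, which tests whether a list's genes move on balance one way, were run beside it. No list passed at the estimated correlation in any comparison. Counts of members that changed come from the fit over all genes, and counts adjusted over the list alone are given beside them.

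Named genes follow a fixed rule. They are the 6 largest rises and 6 largest falls among changed genes with at least 5 CPM (reads scaled to library size) in the higher group and no overlap between the groups, without predicted genes; up to 3 changed members per list in order of p; and a panel of 11 genes whatever their p. The text names part of this set.

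The test was checked on simulated data with the libraries' depths, the same spread for all genes and 200 changed genes. Over 20 simulated data sets, changes of 2-fold were recovered for 89.8%, 89.4% and 90.3% of genes on average in the comparisons of old GSH-low with old GSH-high, old GSH-high with young and old GSH-low with young. Changes of 1.5-fold were recovered for 33%, 31.7% and 33.7%, with single sets from 19.4% to 44.8%. False calls were 11.6%, 9.1% and 11.3% of all calls on average and up to 18.4% in single sets, above the nominal 5%. Read recovery was 100% in 1500 simulated genes (8 zeros), an arithmetic check.

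Alternatives were other scalings (median-of-ratios size factors, library size only), filters, a pseudocount of 0.1, limma-voom on the recovered reads, the 4 libraries of each comparison alone, the replicate number as a block, and each library left out in turn. Chosen after the data were seen were setting replaced zeros back to 0 and removing a smooth trend over gene length and GC content (loess, span 0.3, 10535 genes or 99.3% with both values). A DESeq2 Wald test was planned for a file of counts and was not run; limma-voom was the alternative that used the recovered reads. Simulated data with no effect and shared young libraries gave an overlap of age comparisons. All 6 libraries and every column were used. Single values of 3 genes are not reported here; the genes stay in the counts and medians of their lists.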

Results

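RNA was measured in sorted muscle stem cells (satellite cells), the resident cells that rebuild muscle fibres. The 6 libraries fall into young, old GSH-high and old GSH-low groups, with 2 libraries in each. GSH is reduced glutathione, the most abundant thiol antioxidant of the cell. Per the labels nearly all young cells stained as GSH-high, and the young group was kept whole. Reads recovered from the deposited RPKM totalled 63.12 M and 60.06 M in the young libraries, 68.79 M and 60.76 M in old GSH-high and 50.71 M and 47.0 M in old GSH-low. A gene with 0 reads may have up to 3, which is 0.0436 to 0.0638 CPM (reads scaled to library size) depending on the library; this floor covers counting error only. The 10 most abundant genes took 5.621% to 6.594% of the reads. The first principal component held 72.7% of the variance and separated young from old libraries, and the next held 16.8% and separated the old fractions from each other. Every p-value rests on 2 libraries per group. Per the labels a young library came from 1 animal and an old one from 2 pooled animals, and whether the old fractions share pools is not stated. Positions are on GRCm38.

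Old GSH-low cells were compared with old GSH-high cells to ask how cells of one age differ with their glutathione content. Genes of tendon cells were higher in old GSH-low. Tnmd (tenomodulin, a membrane protein of tendon cells; chromosome X, 133850980 to 133865577) averaged 129.9 ± 8.55 RPKM (SD, n = 2) against 28.4 ± 1.68, a log2 fold change of 2.15 ± 0.13 (SE; adjusted p = 4.97e-05). Chad (chondroadherin, a cartilage and tendon matrix protein) averaged 249.2 ± 3.26 against 63.2 ± 1.77 RPKM, and Cilp2 (a cartilage matrix protein) 23.3 ± 1.71 against 4.33 ± 1.02. All 11 measured tenocyte markers rose, also when adjusted over the list alone (11), with a median log2 fold change of 1.87 (camera adjusted p = 3.41e-21). The list had adjusted p = 0.217 with an estimated correlation.

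Endothelial genes were lower in old GSH-low than in old GSH-high. Fabp4 (a fatty acid carrier of capillary endothelium and fat cells; chromosome 3, 10204088 to 10208576) averaged 2.92 ± 0.31 RPKM (SD, n = 2) against 21.1 ± 0.414, a log2 fold change of -2.49 ± 0.09 (adjusted p = 5.32e-06). Ly6c1 changed by -2.49 ± 0.13 and Cldn5 (claudin-5, an endothelial tight junction protein) by -1.87 ± 0.11. Of 19 measured endothelial markers 18 fell, 1 did not pass, and 19 fell when adjusted over the list alone, with a median of -1.19 (camera adjusted p = 3.75e-29; adjusted p = 0.217 with an estimated correlation). The endothelial selectins Sele and Selp, which catch leukocytes on the vessel wall, fell by 2.81 ± 0.22 and 2.65 ± 0.33 on the log2 scale. Ly6a, which encodes the Sca1 antigen that the sort excluded, averaged 5.74 ± 1.14 against 26.4 ± 2.18 RPKM. On the fitted log2(RPKM + 1) scale the largest fall was that of Cfd (adipsin, a complement protease of fat cells; chromosome 10, 79890853 to 79892655), from 50.8 ± 12.6 to 1.11 ± 0.396 RPKM (log2 fold change -4.61 ± 0.18, adjusted p = 5.50e-06), and Cidec (a lipid droplet protein) changed by -2.61 ± 0.17, a 49.8-fold fall in mean RPKM beside 45.6-fold for Cfd. Sbpl changed by -4.56 ± 0.99 (adjusted p = 0.0328), but its level rested on old GSH-high replicate 1, with 120.0 RPKM against 6.06 in replicate 2. The Sbpl call ended without old GSH-low replicate 1 (adjusted p = 0.122) or replicate 2 (adjusted p = 0.149) and with limma-voom (adjusted p = 0.233), and without old GSH-high replicate 1 the change was -2.51.

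Markers of further cell types moved as well. Myofibre markers rose in 7 of 11 with 4 that did not pass, 7 also adjusted over the list alone. Their median was 0.87 (camera adjusted p = 2.01e-09; adjusted p = 0.217 with an estimated correlation). Among them Tnnt3 (fast troponin T) averaged 9.22 ± 0.105 RPKM (SD, n = 2) in old GSH-low and 2.47 ± 0.0785 in old GSH-high, and Acta1 (skeletal alpha-actin) 23.8 ± 0.0953 and 11.2 ± 0.455. Smooth muscle and pericyte markers rose in 7 of 13, 7 adjusted over the list alone, among them Rgs5 by 0.78 ± 0.10 and Pdgfrb by 1.07 ± 0.15. Their median was 0.45 (camera adjusted p = 0.000391; adjusted p = 0.292 with an estimated correlation). Of 20 markers of fibro-adipogenic progenitors, the connective tissue cells between the fibres, 5 rose and 4 fell, 5 and 5 adjusted over the list alone (camera adjusted p = 0.915; adjusted p = 0.968 with an estimated correlation). Serpinf1 rose by 1.48 ± 0.10 and Ly6a fell by 2.03 ± 0.13. Of 9 Schwann cell markers 4 rose and 1 fell, 6 and 3 adjusted over the list alone (camera adjusted p = 0.0614; adjusted p = 0.651 with an estimated correlation). The list was called up without old GSH-low replicate 2 (adjusted p = 0.00275), with a replicate block (0.0262), with no filter (0.0290) and with the length and GC trend removed (0.0457). Of 10 macrophage markers 1 rose (Laptm5, by 1.81 ± 0.14) and 1 fell, 1 and 1 adjusted over the list alone (camera adjusted p = 0.694; adjusted p = 0.938 with an estimated correlation).

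**Figure D1:**
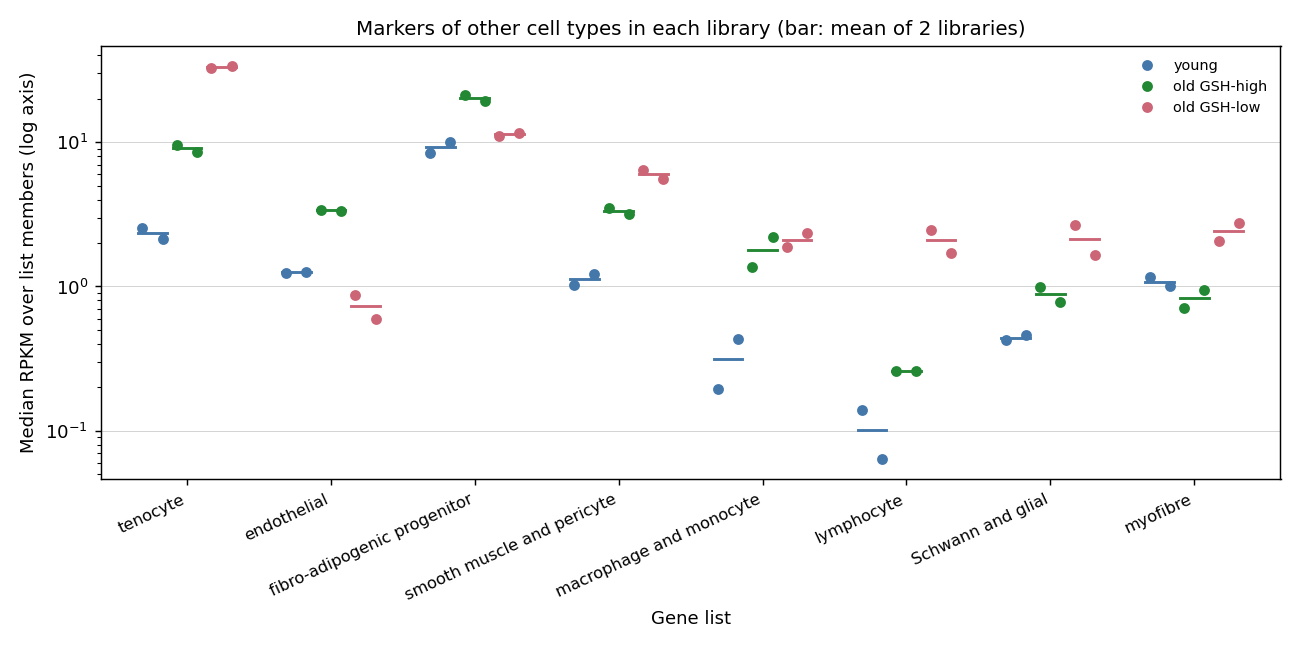
Median RPKM (log axis) over the members of 8 marker lists found in the table, tested or not; each dot is 1 library and each bar the mean of the 2 libraries of a group. Tenocyte medians were 2.55 and 2.15 in young, 9.58 and 8.51 in old GSH-high and 32.8 and 33.9 in old GSH-low, and endothelial medians were highest in old GSH-high (3.37 and 3.36) and lowest in old GSH-low (0.878 and 0.591).

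Genes of antigen presentation by MHC class II were higher in old GSH-low. Cd74 (the invariant chain that guides class II molecules; chromosome 18, 60803848 to 60812652) averaged 95.6 ± 3.92 RPKM (SD, n = 2) against 14.8 ± 2.92, a log2 fold change of 2.63 ± 0.14 (adjusted p = 3.07e-05). H2-Ab1 (a class II beta chain) averaged 27.0 ± 2.04 against 4.80 ± 0.971 RPKM, and H2-DMb2 4.31 ± 0.326 against 0.0952 ± 0.0878, a 45.3-fold rise that the added 1 shrinks to 2.28 ± 0.11 on the log2 scale. Of 19 measured MHC genes 7 rose and none fell, 7 adjusted over the list alone (median 0.12, camera adjusted p = 4.60e-05; adjusted p = 0.217 with an estimated correlation); those 7 were the class II genes. Lymphocyte markers moved with them. Cd79a (a B-cell receptor subunit) averaged 8.60 ± 1.20 RPKM in old GSH-low and 1.68 ± 0.0731 in old GSH-high. Of 5 lymphocyte markers 3 rose, among them Cd79a and Cd79b, and 5 when adjusted over the list alone. Their median was 1.56 (camera adjusted p = 2.75e-08; adjusted p = 0.217 with an estimated correlation). Ccr7 (a chemokine receptor of lymphocytes and dendritic cells) averaged 8.74 ± 0.613 against 0.768 ± 0.704 RPKM.

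Immediate early genes, which respond within minutes to stimuli and to tissue dissociation, were higher in old GSH-low. Fos (a subunit of the AP-1 transcription factor; chromosome 12, 85473890 to 85477273) averaged 890.2 ± 0.856 RPKM (SD, n = 2) against 411.5 ± 12.9, a log2 fold change of 1.11 ± 0.10 (adjusted p = 0.000253). Socs3 (an inhibitor of cytokine signalling) rose by 0.98 ± 0.11 and Zfp36 (a protein that speeds the decay of inflammatory mRNAs) by 0.75 ± 0.09. Of 30 measured members 14 rose and 16 did not pass, and 21 rose when adjusted over the list alone. Their median was 0.39 (camera adjusted p = 4.78e-14; adjusted p = 0.292 with an estimated correlation). Secreted inflammatory and senescence-related factors rose in 12 of 37 and fell in 3, 17 and 5 adjusted over the list alone. Their median was 0.27 (camera adjusted p = 7.05e-05; adjusted p = 0.484 with an estimated correlation). Among them Il6 (interleukin-6) averaged 184.6 ± 17.5 against 79.0 ± 2.05 RPKM, Mmp3 (stromelysin-1, a matrix protease) 175.6 ± 10.8 against 60.0 ± 1.04, and Cxcl10 (a chemokine induced by interferon) 34.5 ± 3.33 against 14.2 ± 1.43. These rises stood beside medians of 1.87 for the tenocyte, 1.56 for the lymphocyte and 0.45 for the smooth muscle and pericyte markers. Mmp13 (collagenase-3; chromosome 9, 7272514 to 7283331) had the largest rise of the named genes on the fitted log2(RPKM + 1) scale, from 2.15 ± 0.125 to 23.4 ± 3.57 RPKM (log2 fold change 2.95 ± 0.29, adjusted p = 0.000436), followed by Ptx4 (a pentraxin), from 2.40 ± 0.16 to 20.7 ± 0.0667. By ratio of mean RPKM H2-DMb2 (45.3-fold) and Cd79b (53.6-fold) rose more than Mmp13 (10.9-fold). Targets of NF-kappa B, the transcription factor of inflammatory signalling, rose in 6 of 26, 10 with 1 fall adjusted over the list alone. Their median was 0.19 (camera adjusted p = 0.00118; adjusted p = 0.494 with an estimated correlation).

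Extracellular matrix genes rose in 7 of 43 with 36 that did not pass, 7 adjusted over the list alone. Their median was 0.11 (camera adjusted p = 0.00553; adjusted p = 0.680 with an estimated correlation). Dcn (decorin, a collagen-binding proteoglycan) averaged 443.3 ± 54.8 RPKM (SD, n = 2) in old GSH-low and 174.3 ± 15.7 in old GSH-high, and Fbln1 (fibulin-1) rose by 1.5 ± 0.14. Both moved beside the tenocyte markers, whose median was 1.87. Among interferon-stimulated genes, the antiviral programme, 7 of 42 rose and 2 fell, 8 and 2 adjusted over the list alone; Ifit3 rose by 0.85 ± 0.10 and Ifit1 by 0.81 ± 0.10 (camera adjusted p = 0.0614; adjusted p = 0.651 with an estimated correlation). That list was called up without old GSH-high replicate 1 (adjusted p = 0.0112), without old GSH-low replicate 2 (0.00735) and with the length and GC trend removed (0.0352). Heat shock chaperones rose in 3 of 21, 4 adjusted over the list alone (camera adjusted p = 0.0581; adjusted p = 0.651 with an estimated correlation). They were called up without young replicate 1 (adjusted p = 0.0387) or 2 (0.0390), without old GSH-low replicate 2 (0.0243), under library size only (0.0449), with a pseudocount of 0.1 (0.0473) and with the length and GC trend removed (0.0126). Proteasome genes had a median of -0.18 with none of 33 past the test, 0 adjusted over the list alone (camera adjusted p = 4.55e-06; adjusted p = 0.651 with an estimated correlation). Genes of G2 and mitosis had a median of -0.40 with none of 14 past the test, 5 falls adjusted over the list alone (camera adjusted p = 0.000241; adjusted p = 0.651 with an estimated correlation).

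Few genes that make and use glutathione passed the test between the fractions that were sorted on it. Gclc and Gclm (the catalytic and modifier subunits of glutamate-cysteine ligase, the rate-limiting enzyme of glutathione synthesis) had log2 fold changes of -0.11 ± 0.11 and -0.23 ± 0.08, neither past the test (adjusted p = 0.657 and 0.176). Slc7a11 (the cystine importer) averaged 0.366 ± 0.0187 RPKM (SD, n = 2) in old GSH-low and 0.703 ± 0.0322 in old GSH-high (adjusted p = 0.121). Limma-voom called it, with a log2 fold change of -0.94 (adjusted p = 0.00718) where the reported fit had -0.32. Gss and Gsr, which complete glutathione and reduce its disulfide, had -0.12 ± 0.09 and -0.14 ± 0.11, and the peroxidases Gpx1 and Gpx4 had 0.02 ± 0.11 and 0.19 ± 0.12. Of 21 glutathione synthesis and turnover genes 1 rose, Anpep (aminopeptidase N), by 0.53 ± 0.11 from 0.730 RPKM, and none fell; 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.133; adjusted p = 0.651 with an estimated correlation). The list was called down without old GSH-low replicate 1 (adjusted p = 0.0463). The Anpep call ended without old GSH-high replicate 2 (adjusted p = 0.208), old GSH-low replicate 1 (adjusted p = 0.166) or old GSH-low replicate 2 (adjusted p = 0.0827), and with a pseudocount of 0.1 (log2 fold change 0.95, adjusted p = 0.0834). None of 29 peroxidases, transferases and glutaredoxins passed, 0 adjusted over the list alone (median -0.12, camera adjusted p = 0.0405; adjusted p = 0.695 with an estimated correlation), and that list's call ended without old GSH-high replicate 2 (adjusted p = 0.0816) or old GSH-low replicate 1 (adjusted p = 0.205).

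Genes that supply NADPH, the reductant that keeps glutathione reduced, had a median of -0.15 (17 measured, 2 fell, 2 adjusted over the list alone; camera adjusted p = 0.00497; adjusted p = 0.289 with an estimated correlation). The 2 were G6pdx and Pgd, the dehydrogenases of the pentose phosphate pathway. G6pdx averaged 7.93 ± 0.188 RPKM (SD, n = 2) in old GSH-low and 12.2 ± 0.101 in old GSH-high (log2 fold change -0.56 ± 0.08, adjusted p = 0.00413), and Pgd changed by -0.41 ± 0.09 (adjusted p = 0.0351). With Aldh3a1 (an aldehyde dehydrogenase, -0.37 ± 0.08, adjusted p = 0.0321) they were the 3 of 32 targets of NRF2, the master regulator of antioxidant genes, that fell; 5 fell adjusted over the list alone. Their median was -0.11 (camera adjusted p = 0.00779; adjusted p = 0.651 with an estimated correlation). Without old GSH-high replicate 2 the G6pdx call ended (adjusted p = 0.0514). Without any 1 of the 4 old libraries the calls of Pgd (adjusted p from 0.0982 to 0.266) and Aldh3a1 (0.182 to 0.248) ended. With the replicate number as a block they ended too (0.0584 and 0.0855), and for Aldh3a1 also with the block in old samples only (0.0661).

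Pax7 (the transcription factor that marks satellite cells) averaged 11.9 ± 1.03 RPKM (SD, n = 2) in old GSH-low and 8.37 ± 0.397 in old GSH-high (log2 fold change 0.46 ± 0.09, adjusted p = 0.0225). With Hes1 (a Notch effector, 0.48 ± 0.11, adjusted p = 0.0351) it was one of 2 of 40 genes of stem cell identity and quiescence that rose; Adgrf5 fell by 1.46 ± 0.16, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.664; adjusted p = 0.812 with an estimated correlation). Without any 1 of the 4 old libraries the calls of Pax7 (adjusted p from 0.0548 to 0.202) and Hes1 (0.118 to 0.256) ended. The Hes1 call also ended with the replicate number as a block over all samples (adjusted p = 0.0590) or in old samples only (0.0517). Myod1 (the myogenic determination factor) averaged 612.0 ± 25.4 against 817.9 ± 83.9 RPKM and missed the test (log2 fold change -0.42 ± 0.10, adjusted p = 0.0542). It passed without young replicate 1 (adjusted p = 0.0310) or replicate 2 (adjusted p = 0.0313), scaled by library size only (0.0406), with limma-voom (0.0180), in the 4 old libraries alone (0.0317) and with the length and GC trend removed (0.0142). Vcam1, a sort marker, had -0.18 ± 0.09 and Cdkn1a (the cell cycle inhibitor p21) 0.27 ± 0.12, neither past the test (adjusted p = 0.303 and 0.254). Genes of myogenic commitment fell in 2 of 23, 1 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.374; adjusted p = 0.694 with an estimated correlation).

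In all, 571 of 10609 genes changed between the old fractions: 392 rose and 179 fell in old GSH-low, and 111 rose and 62 fell by at least 2-fold. Of the 42 lists 19 were called, 10 up and 9 down, and 0 at an estimated correlation, where fry called 9. The count of genes was 862 without young replicate 1, 863 without young replicate 2, 371 without old GSH-high replicate 1, 312 without old GSH-high replicate 2, 324 without old GSH-low replicate 1 and 367 without old GSH-low replicate 2. Limma-voom, which adds no 1 RPKM, gave log2 fold changes over 1.5 times as large for Cd79b (5.98), H2-DMb2 (5.82), Ccr7 (3.92), Cidec (-5.56), Sbpl (-6.96), Anpep (1.04) and Slc7a11 (-0.94). Among called lists named above, leaving out 1 library moved the medians of G2 and mitosis (-0.626 and -0.222 without old GSH-high replicate 1 and 2), MHC genes (0.078 without old GSH-low replicate 1), NRF2 targets (-0.068 without old GSH-high replicate 1), and peroxidases, transferases and glutaredoxins (-0.072 without old GSH-low replicate 1) by over 1.5 times. The extracellular matrix median was 0.06 without old GSH-high replicate 2 and 0.062 and 0.07 without old GSH-low replicate 1 and 2.

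**Figure D2:**
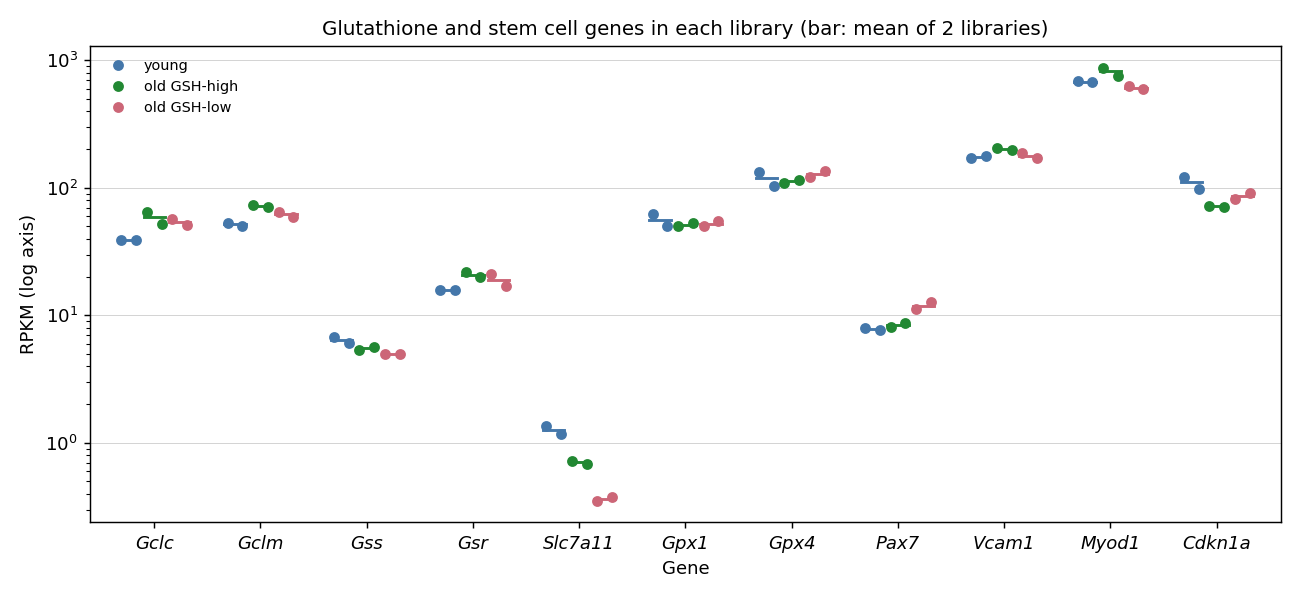
RPKM (log axis) of 11 genes of glutathione metabolism and stem cell state; each dot is 1 library and each bar the mean of the 2 libraries of a group. Slc7a11 averaged 1.27 RPKM in young, 0.703 in old GSH-high and 0.366 in old GSH-low, and Gclc 38.9, 58.7 and 54.1.

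Old GSH-high cells were compared with young cells, which were nearly all GSH-high, to ask what changes with age at a high glutathione content. Interferon-stimulated genes were higher in old GSH-high. Ifit3 (an antiviral RNA-binding protein; chromosome 19, 34583531 to 34588731) averaged 7.06 ± 0.445 RPKM (SD, n = 2) in old GSH-high and 1.52 ± 0.0702 in young, a log2 fold change of 1.68 ± 0.10 (adjusted p = 8.14e-06). Ifi204 rose by 2.27 ± 0.11 and Rtp4 by 1.75 ± 0.09. Of 42 measured members 38 rose and none fell, 38 and 1 adjusted over the list alone. Their median was 0.85 (camera adjusted p = 1.60e-20; adjusted p = 0.344 with an estimated correlation). MHC genes rose in 15 of 19, 16 adjusted over the list alone; H2-Q6 (a class I gene) averaged 58.8 ± 1.16 against 19.9 ± 0.0151 RPKM and Cd74 14.8 ± 2.92 against 2.52 ± 0.483. Their median was 0.81 (camera adjusted p = 1.00e-09; adjusted p = 0.344 with an estimated correlation). Macrophage markers moved with them: 10 of 10 rose, 10 adjusted over the list alone, among them Lyz2 (lysozyme, by 2.53 ± 0.24), with a median of 1.16 (camera adjusted p = 1.15e-07; adjusted p = 0.377 with an estimated correlation).

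Markers of tenocytes and fibro-adipogenic progenitors were higher in old GSH-high than in young. Fmod (fibromodulin, a tendon matrix proteoglycan; chromosome 1, 134037254 to 134048277) averaged 316.7 ± 54.9 RPKM (SD, n = 2) against 11.8 ± 2.21, a log2 fold change of 4.63 ± 0.15 (adjusted p = 6.85e-07). Thbs4 (thrombospondin-4, a tendon and muscle matrix protein) averaged 261.1 ± 57.9 against 10.4 ± 2.23 RPKM and Chad 63.2 ± 1.77 against 3.43 ± 0.996. Of 11 tenocyte markers 10 rose, 10 adjusted over the list alone. Their median was 2.53 (camera adjusted p = 1.18e-10; adjusted p = 0.344 with an estimated correlation). Markers of fibro-adipogenic progenitors rose in 15 of 20 and fell in 1, 16 and 1 adjusted over the list alone, among them Dcn by 3.38 ± 0.13. Their median was 1.22 (camera adjusted p = 4.41e-08; adjusted p = 0.501 with an estimated correlation). Smooth muscle and pericyte markers rose in 9 of 13 and fell in 3, 9 and 3 adjusted over the list alone (median 0.51, camera adjusted p = 0.0133; adjusted p = 0.501 with an estimated correlation), and the call ended with no filter on low values (adjusted p = 0.0852). Extracellular matrix genes split: 16 of 43 rose and 15 fell, 16 and 17 adjusted over the list alone, with a median of -0.04 where the mean was 0.16 and camera pointed up (camera adjusted p = 0.899; adjusted p = 0.987 with an estimated correlation). Of that list's collagens, Col5a1 fell by 1.30 ± 0.09.

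Endothelial markers rose in 19 of 19, 19 adjusted over the list alone, among them Fabp4 by 1.18 ± 0.09 and Esam (a junction protein of endothelium) by 1.01 ± 0.12. Their median was 0.81 (camera adjusted p = 1.18e-10; adjusted p = 0.501 with an estimated correlation). Cfd had the largest rise of the comparison on the fitted log2(RPKM + 1) scale, 50.8 ± 12.6 RPKM (SD, n = 2) in old GSH-high against 0 and 4 reads in the young libraries (log2 fold change 5.60 ± 0.18, adjusted p = 5.23e-07). Sbpl had 0 reads in both young libraries and was at least 1150-fold higher in old GSH-high against a floor of 3 reads per library, but 7331 of its reads came from old GSH-high replicate 1 and 331 from replicate 2. Its call ended with limma-voom (adjusted p = 0.0635). Angptl7 (a secreted angiopoietin-like protein) averaged 101.4 ± 8.21 against 2.63 ± 0.271 RPKM and Cyp26a1 (the enzyme that degrades retinoic acid) 73.2 ± 3.74 against 2.38 ± 0.444. Neutrophil markers rose in 6 of 6, 6 adjusted over the list alone, among them Camp (an antimicrobial peptide, 2.48 ± 0.517 against 0.228 ± 0.107 RPKM), with a median of 1.90 (camera adjusted p = 0.000436; adjusted p = 0.501 with an estimated correlation). Schwann cell markers rose in 3 of 9, 5 adjusted over the list alone. Their median was 0.34 (camera adjusted p = 0.00722; adjusted p = 0.501 with an estimated correlation). Erythroid markers rose in 4 of 5, 4 adjusted over the list alone, among them Hba-a2 (alpha-globin) by 1.56 ± 0.22 (camera adjusted p = 0.0321; adjusted p = 0.523 with an estimated correlation); the call ended without young replicate 2 (adjusted p = 0.137) and under library size only (adjusted p = 0.0510). Lymphocyte markers rose in 2 of 5 and fell in 1, 2 and 1 adjusted over the list alone (camera adjusted p = 0.751; adjusted p = 0.845 with an estimated correlation).

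Heat shock chaperones and immediate early genes were lower in old GSH-high than in young. Hspa1a (the inducible chaperone HSP70; chromosome 17, 34969190 to 34972156) averaged 242.3 ± 16.6 RPKM (SD, n = 2) against 1086 ± 26.9, a log2 fold change of -2.16 ± 0.10 (adjusted p = 3.22e-06), its near-identical neighbour Hspa1b changed by -2.03 ± 0.10, and Dnajb1 (an HSP40 cochaperone) by -1.96 ± 0.10. Of 21 measured chaperones 16 fell and none rose, 16 adjusted over the list alone. Their median was -0.72 (camera adjusted p = 2.18e-11; adjusted p = 0.377 with an estimated correlation). Fos averaged 411.5 ± 12.9 against 951.0 ± 76.2 RPKM, and Egr2 (a zinc finger transcription factor) changed by -1.10 ± 0.08. Of 30 immediate early genes 20 fell and 6 rose, 20 and 6 adjusted over the list alone, among the rises Nr4a2 (an orphan nuclear receptor) by 1.23 ± 0.10. Their median was -0.42 (camera adjusted p = 0.000173; adjusted p = 0.501 with an estimated correlation). Genes of the unfolded protein response of the endoplasmic reticulum fell in 12 of 25, 12 adjusted over the list alone. Their median was -0.27 (camera adjusted p = 0.00350; adjusted p = 0.501 with an estimated correlation).

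Genes of glutathione synthesis and NRF2 targets were higher in old GSH-high than in young. Gclc averaged 58.7 ± 9.18 RPKM (SD, n = 2) against 38.9 ± 0.024, a log2 fold change of 0.57 ± 0.11 (adjusted p = 0.00609), and Gclm 72.6 ± 1.87 against 51.6 ± 1.89 (0.49 ± 0.08, adjusted p = 0.00313). Dpep1 (a dipeptidase that cleaves a breakdown product of glutathione) rose by 2.12 ± 0.15, Cbs (an enzyme of cysteine synthesis) by 1.01 ± 0.11 and Slc3a2 (the heavy chain of the cystine importer) by 0.55 ± 0.09. Of 21 measured members 10 rose and 1 fell, 10 and 2 adjusted over the list alone. Their median was 0.26 (camera adjusted p = 0.00791; adjusted p = 0.501 with an estimated correlation). The 1 that fell was Slc7a11, by 0.41 ± 0.10 (adjusted p = 0.0154), and Gsr rose by 0.38 ± 0.11 (adjusted p = 0.0298). Without old GSH-high replicate 1 the calls of Gclc (adjusted p = 0.0615), Gsr (0.200) and Slc7a11 (0.0696) ended. Without old GSH-high replicate 2 those of Gsr (0.0682) and Slc7a11 (0.0809) ended, without young replicate 1 those of Gsr (0.0747) and Slc7a11 (0.0821), and without young replicate 2 that of Gsr (0.0518). NRF2 targets rose in 16 of 32 and fell in 3, 17 and 3 adjusted over the list alone. Their median was 0.36 (camera adjusted p = 0.000119; adjusted p = 0.501 with an estimated correlation). Hmox1 (heme oxygenase-1) averaged 1415 ± 111 against 628.6 ± 44.3 RPKM, Aldh3a1 rose by 1.99 ± 0.08 and Akr1b8 (an aldo-keto reductase) by 1.20 ± 0.11.

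Among other redox genes of the same comparison, 5 of 29 peroxidases, transferases and glutaredoxins rose and 8 fell, 6 and 11 adjusted over the list alone. Their median of 0.03 and mean of 0.02 were positive where camera pointed down (camera adjusted p = 0.952; adjusted p = 0.987 with an estimated correlation). Gss had -0.18 ± 0.09, Gpx1 -0.11 ± 0.11 and Gpx4 -0.07 ± 0.12, none past the test (adjusted p = 0.162, 0.474 and 0.707). The list of thioredoxin, peroxiredoxin, superoxide dismutase and catalase genes had 2 rises and 4 falls among 25, 1 and 2 adjusted over the list alone. Their median was -0.16 (camera adjusted p = 0.0321; adjusted p = 0.523 with an estimated correlation). Txnrd1 (thioredoxin reductase 1) rose by 0.66 ± 0.11. That list's call ended without young replicate 1 (adjusted p = 0.272), without old GSH-high replicate 2 (adjusted p = 0.0537) and with the length and GC trend removed (adjusted p = 0.107). Of 17 NADPH supply genes 6 rose and 3 fell, 8 and 4 adjusted over the list alone, among the falls Idh2 (the mitochondrial NADP isocitrate dehydrogenase) by 0.96 ± 0.09 (camera adjusted p = 0.380; adjusted p = 0.523 with an estimated correlation). Methionine, one-carbon and polyamine genes rose in 6 of 28 and fell in 8, 7 and 8 adjusted over the list alone, among the falls Psat1 (an enzyme of serine synthesis) by 0.77 ± 0.09 (camera adjusted p = 0.423; adjusted p = 0.523 with an estimated correlation). Glycolysis genes rose in 4 of 20 and fell in 2, 4 and 2 adjusted over the list alone (camera adjusted p = 0.289; adjusted p = 0.540 with an estimated correlation). The lactate transporters Slc16a3 and Slc16a1 rose by 2.27 ± 0.09 and 1.21 ± 0.10.

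Nuclear-encoded genes of oxidative phosphorylation, the ATP-making chain of mitochondria, fell in 52 of 78, 64 adjusted over the list alone, and none rose. Their median was -0.49 (camera adjusted p = 7.08e-15; adjusted p = 0.501 with an estimated correlation). Ndufs6 (a complex I subunit) averaged 20.2 ± 0.354 RPKM (SD, n = 2) in old GSH-high and 35.6 ± 5.41 in young, and Cox6c (a complex IV subunit) changed by -0.54 ± 0.09. Cytosolic ribosomal protein genes fell in 35 of 81, 52 adjusted over the list alone (median -0.37, camera adjusted p = 1.69e-11; adjusted p = 0.523 with an estimated correlation); Rps26 changed by -0.51 ± 0.09 and Rpl37a by -0.65 ± 0.12. Young replicate 1 stood apart for both groups: the median level of ribosomal protein genes was 159 RPKM there and 123 in young replicate 2, against 101 and 103 in old GSH-high. Without young replicate 1 ribosomal protein genes fell in 6 of 81 (median -0.19) and oxidative phosphorylation genes in 28 of 78 (median -0.32); without young replicate 2 they fell in 74 and 71. None of 8 mitochondrially encoded transcripts passed, 0 adjusted over the list alone. Their median was -0.26 (camera adjusted p = 0.0919; adjusted p = 0.657 with an estimated correlation). It was -0.056 without young replicate 1 and -0.47 without young replicate 2, where the list was called (adjusted p = 0.00117), as it was with a replicate block (0.0473). Proteasome genes fell in 6 of 33, 3 adjusted over the list alone. Their median was -0.19 (camera adjusted p = 0.000404; adjusted p = 0.551 with an estimated correlation). It was -0.082 without young replicate 1 and -0.305 without young replicate 2. The median level was 60.0 RPKM in young replicate 1, 51.8 in young replicate 2 and 51.7 and 51.1 in old GSH-high. Fatty acid oxidation genes fell in 7 of 23 and rose in 1, 8 and 1 adjusted over the list alone. Their median was -0.22 (camera adjusted p = 0.00881; adjusted p = 0.501 with an estimated correlation). Autophagy and lysosome genes fell in 12 of 48 and rose in 3, 12 and 3 adjusted over the list alone. Their median was -0.17 (camera adjusted p = 0.0137; adjusted p = 0.501 with an estimated correlation).

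Secreted inflammatory and senescence-related factors rose in 17 of 37 and fell in 7, 17 and 7 adjusted over the list alone. Their median was 0.34 (camera adjusted p = 0.00930; adjusted p = 0.501 with an estimated correlation). Ccl11 (eotaxin) averaged 261.6 ± 9.44 RPKM (SD, n = 2) in old GSH-high and 17.9 ± 0.536 in young, Mmp3 60.0 ± 1.04 and 1.84 ± 0.521, and Il6 79.0 ± 2.05 and 17.1 ± 2.08. Cdkn1a fell by 0.60 ± 0.12 (adjusted p = 0.00529). Ptgs2 (cyclooxygenase-2) rose by 2.38 ± 0.20 and Perp (a p53 target) by 1.86 ± 0.11. These rises stood beside a median of 2.53 for the tenocyte and 1.22 for the fibro-adipogenic markers.

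Of 40 genes of stem cell identity and quiescence 11 fell and 5 rose in old GSH-high, 11 and 5 adjusted over the list alone (camera adjusted p = 0.261; adjusted p = 0.523 with an estimated correlation). Gas1 (a growth arrest protein) averaged 63.0 ± 3.04 RPKM (SD, n = 2) against 143.7 ± 2.41 in young, and Msc (musculin, a repressor of myogenic genes) 73.1 ± 0.78 against 166.5 ± 16.3. Pax7 had a log2 fold change of 0.09 ± 0.09, Vcam1 0.22 ± 0.09 and Myod1 0.26 ± 0.10, none past the test (adjusted p = 0.488, 0.0823 and 0.0875). Scaled by library size only, Vcam1 (adjusted p = 0.0322) and Myod1 (0.0329) passed, and Myod1 also passed with limma-voom (0.0453) and with the length and GC trend removed (0.0153). Genes of myogenic commitment fell in 9 of 23 and rose in 2, 9 and 2 adjusted over the list alone, among the falls Chrna1 (an acetylcholine receptor subunit) by 1.40 ± 0.12. Their median was -0.15 (camera adjusted p = 0.0421; adjusted p = 0.501 with an estimated correlation). That call ended without young replicate 1 (adjusted p = 0.0530) or replicate 2 (adjusted p = 0.0549), and with the length and GC trend removed (adjusted p = 0.0595). Genes of G2 and mitosis fell in 10 of 14, 10 adjusted over the list alone, among them Mki67 (the proliferation marker Ki-67, 0.640 ± 0.342 against 1.75 ± 0.0852 RPKM) and Ckap2 by 0.80 ± 0.10. Their median was -0.58 (camera adjusted p = 0.000136; adjusted p = 0.501 with an estimated correlation). Further falls on the fitted log2(RPKM + 1) scale were those of Col26a1 (a collagen), Tac4 (a tachykinin precursor) and Dgkg (a diacylglycerol kinase), by 1.99 ± 0.11, 1.99 ± 0.18 and 1.97 ± 0.11.

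In all, 3051 of 10609 genes changed between old GSH-high and young: 1598 rose and 1453 fell, and 342 rose and 90 fell by at least 2-fold. With libraries scaled by size only, 1935 rose and 1124 fell, which moved the share that rose from 52.4% to 63.3% and the median of all genes from -0.004 to 0.047. Of the 42 lists 24 were called, 13 up and 11 down, and 0 at an estimated correlation, where fry called 22. The count of genes was 1493 without old GSH-high replicate 1 and 1816 without old GSH-high replicate 2. Limma-voom gave log2 fold changes over 1.5 times as large for Sbpl (11.53), Cfd (10.85), Camp (5.36), Ifi204 (4.13), Perp (2.80), Mki67 (-1.58) and Slc7a11 (-0.85), and that of Sbpl was 2.74 without old GSH-high replicate 1. Leaving out 1 library moved the medians of secreted factors (0.174 without young replicate 2), G2 and mitosis (-0.355 without old GSH-high replicate 1), the thioredoxin list (-0.031 without young replicate 1) and myogenic commitment (-0.238 without young replicate 2) by over 1.5 times.

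**Figure D3:**
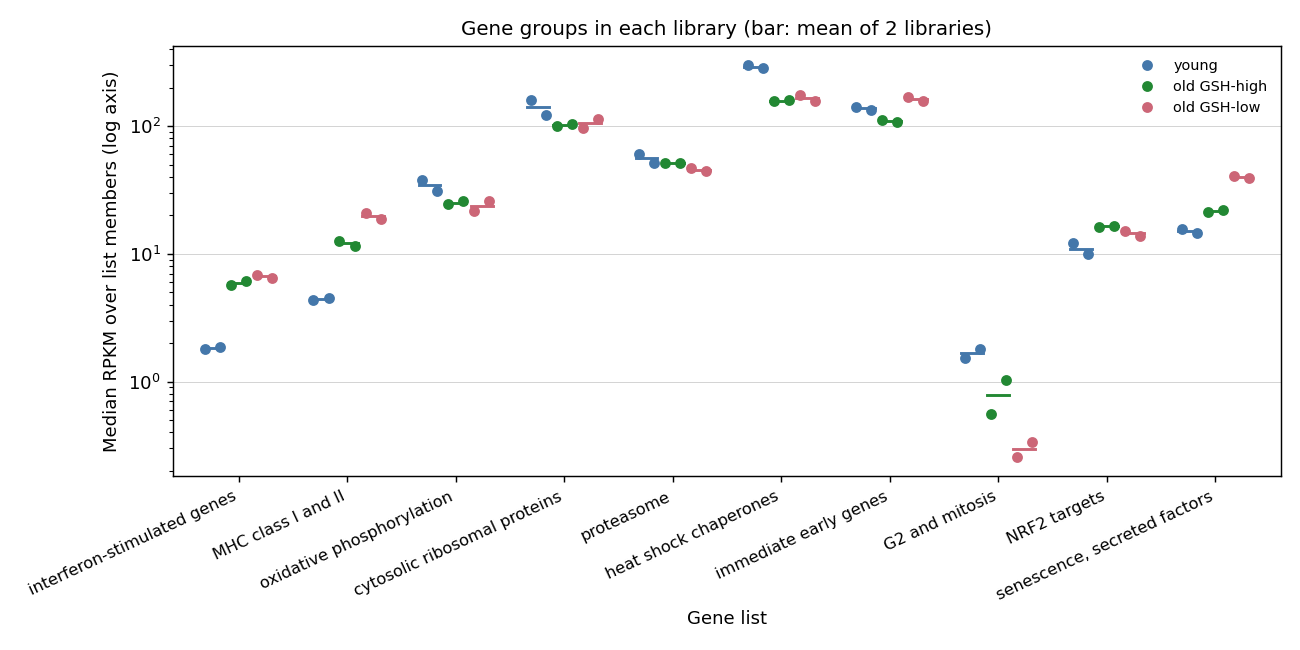
Median RPKM (log axis) over the members of 10 gene lists found in the table, tested or not; each dot is 1 library and each bar the mean of the 2 libraries of a group. The ribosomal protein medians were 159 and 123 in the young libraries, 101 and 103 in old GSH-high and 97.2 and 114 in old GSH-low, and interferon-stimulated medians were lowest in both young libraries.

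Old GSH-low cells were compared with young cells to ask how aged cells of low glutathione differ from young cells. Tenocyte markers were higher in old GSH-low. Fmod averaged 1274 ± 128 RPKM (SD, n = 2) in old GSH-low and 11.8 ± 2.21 in young, a log2 fold change of 6.65 ± 0.15 (adjusted p = 3.52e-08). Thbs4 averaged 1013 ± 147 against 10.4 ± 2.23 RPKM, and Comp (cartilage oligomeric matrix protein; chromosome 8, 70373558 to 70382066) 133.6 ± 6.23 against 2.49 ± 1.00. Chad rose by 5.84 ± 0.14 and Angptl7 by 6.06 ± 0.12. All 11 tenocyte markers rose, 11 adjusted over the list alone. Their median was 4.31 (camera adjusted p = 2.97e-14; adjusted p = 0.297 with an estimated correlation). Markers of fibro-adipogenic progenitors rose in 12 of 20 and fell in 3, 13 and 3 adjusted over the list alone, among them Dcn by 4.72 ± 0.13 and Serpinf1 by 3.03 ± 0.10. Their median was 0.93 (camera adjusted p = 0.000479; adjusted p = 0.461 with an estimated correlation). Col1a1 (type I collagen) rose by 1.78 ± 0.18 while Col3a1 (type III collagen) averaged 95.3 ± 8.58 against 320.1 ± 73.8 RPKM; of 43 extracellular matrix genes 16 rose and 15 fell, 16 and 16 adjusted over the list alone (camera adjusted p = 0.426; adjusted p = 0.836 with an estimated correlation).

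Endothelial markers were lower in old GSH-low than in young, in 12 of 19 with none higher, 12 adjusted over the list alone. Fabp4 changed by -1.32 ± 0.09 and Cldn5 by -1.24 ± 0.11. Their median was -0.47 (camera adjusted p = 0.000226; adjusted p = 0.461 with an estimated correlation). Smooth muscle and pericyte markers rose in 8 of 13 and fell in 3, 9 and 3 adjusted over the list alone, among them Rgs5 by 1.70 ± 0.10. Their median was 0.79 (camera adjusted p = 0.00232; adjusted p = 0.454 with an estimated correlation). Myofibre markers rose in 6 of 11 and fell in 2, 6 and 2 adjusted over the list alone, among them Tnnt3 by 1.91 ± 0.09. Their median was 0.65 (camera adjusted p = 0.0307; adjusted p = 0.461 with an estimated correlation). The myofibre call ended without young replicate 2 (adjusted p = 0.0632) and under library size only (adjusted p = 0.0615). Macrophage markers rose in 10 of 10, 10 adjusted over the list alone. Their median was 1.19 (camera adjusted p = 4.69e-07; adjusted p = 0.431 with an estimated correlation). Neutrophil markers rose in 5 of 6, 5 adjusted over the list alone (camera adjusted p = 0.00627; adjusted p = 0.461 with an estimated correlation). Schwann cell markers rose in 7 of 9, 7 with 1 fall adjusted over the list alone (camera adjusted p = 0.00354; adjusted p = 0.461 with an estimated correlation). Erythroid markers rose in 4 of 5, 4 adjusted over the list alone (camera adjusted p = 0.0145; adjusted p = 0.461 with an estimated correlation), a call that ended without young replicate 2 (adjusted p = 0.0663).

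Interferon-stimulated genes rose in 38 of 42 and none fell, 39 adjusted over the list alone. Their median was 0.93 (camera adjusted p = 2.73e-18; adjusted p = 0.297 with an estimated correlation). Ifit3 averaged 13.5 ± 1.18 RPKM (SD, n = 2) in old GSH-low and 1.52 ± 0.0702 in young, and Ifit1 18.5 ± 0.899 and 2.71 ± 0.31. MHC genes rose in 17 of 19, 18 adjusted over the list alone. Their median was 1.00 (camera adjusted p = 3.08e-12; adjusted p = 0.281 with an estimated correlation). Cd74 rose by 4.79 ± 0.14 and H2-Ab1 by 3.71 ± 0.17. Lymphocyte markers rose in 4 of 5 and fell in 1, 4 and 1 adjusted over the list alone, among them Cd79a by 2.50 ± 0.11. Their median was 1.55 (camera adjusted p = 0.00698; adjusted p = 0.461 with an estimated correlation). Secreted inflammatory and senescence-related factors rose in 21 of 37 and fell in 7, 21 and 8 adjusted over the list alone. Their median was 0.41 (camera adjusted p = 0.000144; adjusted p = 0.461 with an estimated correlation). Mmp3 averaged 175.6 ± 10.8 against 1.84 ± 0.521 RPKM, Ccl11 384.6 ± 8.68 against 17.9 ± 0.536 and Il6 184.6 ± 17.5 against 17.1 ± 2.08, beside medians of 4.31 for the tenocyte and 0.93 for the fibro-adipogenic markers. Immediate early genes rose in 9 of 30 and fell in 8, 10 and 9 adjusted over the list alone, among the rises Nr4a2 by 1.84 ± 0.10 and Socs3 by 1.63 ± 0.11. That list's median of -0.08 was negative where its mean of 0.11 and camera pointed up (camera adjusted p = 0.898; adjusted p = 0.964 with an estimated correlation).

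Proteasome genes fell in 24 of 33 in old GSH-low, 29 adjusted over the list alone, and none rose. Their median was -0.35 (camera adjusted p = 5.71e-08; adjusted p = 0.461 with an estimated correlation). Psmd8 (a subunit of the regulatory particle) averaged 72.6 ± 4.20 RPKM (SD, n = 2) against 121.4 ± 15.3 in young and Psma4 (a core subunit) 28.6 ± 1.47 against 46.1 ± 4.24. Heat shock chaperones fell in 17 of 21, 18 adjusted over the list alone, among them Hspa1a by 1.46 ± 0.10 and Dnajb1 by 1.54 ± 0.10. Their median was -0.76 (camera adjusted p = 2.19e-09; adjusted p = 0.431 with an estimated correlation). Genes of the unfolded protein response fell in 13 of 25 and rose in 1, 15 and 1 adjusted over the list alone, among the falls the folding factors Pdia4 by 0.83 ± 0.11 and Hsp90b1 by 0.61 ± 0.09. Their median was -0.36 (camera adjusted p = 0.000507; adjusted p = 0.461 with an estimated correlation). Genes of G2 and mitosis fell in 13 of 14, 13 adjusted over the list alone. Their median was -0.99 (camera adjusted p = 1.89e-06; adjusted p = 0.461 with an estimated correlation). Mki67 averaged 0.153 ± 0.0169 against 1.75 ± 0.0852 RPKM and Ccnb2 (cyclin B2) 1.82 ± 0.185 against 5.39 ± 0.747, Ckap2 changed by -0.99 ± 0.10, and Pbk (a mitotic kinase) by -2.11 ± 0.25.

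Oxidative phosphorylation genes fell in 66 of 78, 69 adjusted over the list alone, and none rose. Their median was -0.50 (camera adjusted p = 6.17e-14; adjusted p = 0.485 with an estimated correlation). Ndufa9 and Ndufc2 (complex I subunits) changed by -0.68 ± 0.10 and -0.83 ± 0.13. Ribosomal protein genes fell in 43 of 81, 55 adjusted over the list alone, among them Rps26 by 0.54 ± 0.09 and Rpl29 by 0.66 ± 0.12. Their median was -0.37 (camera adjusted p = 2.19e-09; adjusted p = 0.565 with an estimated correlation). The young libraries differed for both groups. Without young replicate 1 the oxidative phosphorylation median was -0.34 and the ribosomal protein median -0.19. Without young replicate 2 these medians were -0.68 and -0.54. Fatty acid oxidation genes fell in 10 of 23, 11 adjusted over the list alone, among them Etfa (an electron transfer flavoprotein) from 150.8 ± 12.0 to 90.0 ± 0.405 RPKM (SD, n = 2) and Acadl (an acyl-CoA dehydrogenase) by 0.60 ± 0.09. Their median was -0.27 (camera adjusted p = 0.000401; adjusted p = 0.431 with an estimated correlation). Idh2 changed by -1.15 ± 0.09 and Psat1 by -0.97 ± 0.09. Of 17 NADPH supply genes 2 rose and 4 fell, 2 and 4 adjusted over the list alone, with a median of 0.03 where the mean was -0.07 and camera pointed down (camera adjusted p = 0.653; adjusted p = 0.742 with an estimated correlation). Glycolysis genes rose in 5 of 20 and fell in 3, 5 and 4 adjusted over the list alone, among the rises Slc16a3 by 2.07 ± 0.09; their median of -0.05 was negative where the mean was 0.15 and camera pointed up (camera adjusted p = 0.624; adjusted p = 0.742 with an estimated correlation).

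In the glutathione genes of the same comparison, Slc7a11 averaged 0.366 ± 0.0187 RPKM (SD, n = 2) in old GSH-low and 1.27 ± 0.128 in young (log2 fold change -0.73 ± 0.10, adjusted p = 0.000690). Gclc rose by 0.46 ± 0.11 (adjusted p = 0.0128) and Gclm by 0.26 ± 0.08 (adjusted p = 0.0417), and Gss fell by 0.30 ± 0.09 (adjusted p = 0.0289). The Gclc call ended without old GSH-low replicate 1 (adjusted p = 0.101). The Gclm call ended without each library except young replicate 1 (adjusted p from 0.0771 to 0.259), and the Gss call without each library except young replicate 2 (adjusted p from 0.0552 to 0.128). Both also ended in the 4 libraries of the comparison alone (0.0885 and 0.0549) and with a replicate block (0.0708 and 0.0580), and that of Gss under library size only (0.0638). Gsr had 0.24 ± 0.11 (adjusted p = 0.112) and passed without old GSH-low replicate 2 (adjusted p = 0.0462), under library size only (0.0493) and with the length and GC trend removed (0.0437). Gpx1 had -0.09 ± 0.11 (adjusted p = 0.536) and Gpx4 0.13 ± 0.12 (adjusted p = 0.440), the latter past the test without young replicate 1 (adjusted p = 0.0440). Of 21 measured members 9 rose and 3 fell, 9 and 3 adjusted over the list alone. Their median was 0.24 (camera adjusted p = 0.0572; adjusted p = 0.461 with an estimated correlation). The list was called up without old GSH-low replicate 2 (adjusted p = 0.0368) and with a replicate block (0.0495). NRF2 targets rose in 16 of 32 and fell in 4, 17 and 4 adjusted over the list alone, among the rises Aldh3a1 by 1.61 ± 0.08 (median 0.28, camera adjusted p = 0.0115; adjusted p = 0.485 with an estimated correlation), and the call ended without young replicate 2 (adjusted p = 0.0585). The thioredoxin, peroxiredoxin, superoxide dismutase and catalase list fell in 9 of 25 and rose in 3, 9 and 3 adjusted over the list alone (median -0.22, camera adjusted p = 0.0145; adjusted p = 0.485 with an estimated correlation), and the call ended without young replicate 1 (adjusted p = 0.0895).

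Pax7 averaged 11.9 ± 1.03 RPKM (SD, n = 2) in old GSH-low and 7.79 ± 0.204 in young (log2 fold change 0.55 ± 0.09, adjusted p = 0.00206). Of 40 genes of stem cell identity and quiescence 7 rose and 10 fell, 7 and 10 adjusted over the list alone, among the falls Msc by 1.39 ± 0.10 and Gas1 by 0.87 ± 0.08 (camera adjusted p = 0.413; adjusted p = 0.644 with an estimated correlation). Genes of myogenic commitment fell in 12 of 23 and rose in 4, 12 and 4 adjusted over the list alone, among the falls Chrna1 by 1.42 ± 0.12. Their median was -0.28 (camera adjusted p = 0.0214; adjusted p = 0.461 with an estimated correlation). Vcam1 had 0.05 ± 0.09 and Myod1 -0.15 ± 0.10, neither past the test (adjusted p = 0.697 and 0.266). Cdkn1a fell by 0.34 ± 0.12 (adjusted p = 0.0497), a call that ended without each library except young replicate 2 (adjusted p from 0.0812 to 0.258). It also ended under library size only (0.0965), in the 4 libraries alone (0.0841), with a replicate block (0.0751), with no filter (0.0511), with a pseudocount of 0.1 (0.0510) and, at the threshold itself, with replaced zeros set back to 0. Without young replicate 1 the change was -0.172. Col26a1 and the receptor tyrosine kinase Ret were among the largest falls on the fitted log2(RPKM + 1) scale, by 2.22 ± 0.11 and 2.07 ± 0.10, with Atp2a3 (a calcium pump) by 2.00 ± 0.14, Dgkg by 1.95 ± 0.11 and Ttyh1 (a chloride channel family member) by 1.93 ± 0.08.

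In all, 3901 of 10609 genes changed between old GSH-low and young: 1919 rose and 1982 fell, and 473 rose and 119 fell by at least 2-fold. With libraries scaled by size only, 2259 rose and 1487 fell, which moved the share that rose from 49.2% to 60.3% and the median of all genes from -0.021 to 0.037. Of the 42 lists 23 were called, 13 up and 10 down, and 0 at an estimated correlation, where fry called 23. The count of genes was 2068 without old GSH-low replicate 1. Limma-voom gave log2 fold changes over 1.5 times as large for Pbk (-4.99), Mki67 (-3.51) and Slc7a11 (-1.79).

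The age comparisons shared 2444 genes called in the same direction, 1279 up and 1165 down, and 40 in opposite directions. Independent lists of these sizes would share 560.5 and 561.4. Both comparisons use the same 2 young libraries, which alone makes the lists overlap. With no effect, 100 simulations gave 1.34 genes in the same direction on average and at most 9. So few calls cannot size that overlap here. The covariance of the log2 fold changes over genes was 0.216, against 0.0114 in those simulations, and their correlation over genes, which are not independent replicates, was 0.85 against 0.50. Dividing the controls would leave 1 young library each and was not done, so part of the excess may come from them. The shared count was 1299 without old GSH-high replicate 1, 1557 without old GSH-high replicate 2 and 1558 without old GSH-low replicate 1. The count in opposite directions was 22 without old GSH-high replicate 1, 20 without old GSH-high replicate 2 and 21 without old GSH-low replicate 2. Of the 392 genes higher in old GSH-low than in old GSH-high, 192 were also higher in old GSH-high than in young, 58 were lower and 142 did not pass. Of the 179 lower ones, 137 were higher in old GSH-high than in young, 10 were lower and 32 did not pass; Fabp4, Cldn5 and Cfd were among the 137.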

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

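The tests of cell mixtures for the tendon-cell and MHC class II genes were chosen only after the results were seen.

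The old fractions differed for 571 genes by the limma test of old GSH-low against old GSH-high. Young cells were not split by GSH, so a differing age effect cannot be tested. For 40 of these genes the age comparisons were called in opposite directions (20 to 29 with 1 library left out): 31 were higher in old GSH-high than in young and lower in old GSH-low than in young, and 9 the reverse. The 31 held 12 endothelial markers, among them Fabp4, Cldn5 and Esam, and the 9 held Acta1, Cxcl10 and Zfp36. The endothelial list as a whole was called up in old GSH-high and down in old GSH-low against young (adjusted p = 0.501 and 0.461 with an estimated correlation, where neither call stands), and its median between the fractions was -1.19 on the log2 scale.

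Tendon-cell markers were higher in old GSH-low than in old GSH-high, and in both than in young. A lower stem cell share in old GSH-low with the same mix of other cells is argued against, since it would raise all their markers. The endothelial median was -1.19 (SD over members 0.58) and the tenocyte 1.87 (SD 0.53). A single tenocyte-like population at different shares in the old fractions is argued against as the only source of all 11 genes. The gain over young in old GSH-low divided by that in old GSH-high ran from 1.66 (Mkx) to 18.41 (Scx). The SD of its log2 was 0.91 where 1 ratio was needed. The ratios of Scx and Col11a1 divide by gains of only 0.205 and 0.294 RPKM. They lay 2.8 and 2.2 standard errors from the best-fitting ratio of 4.24. The misfit rests on Mkx, at 9.03 RPKM where 22.1 was expected (-7.4 standard errors), and Cilp2, at 23.3 where 10.7 was expected (5.4). The other 9 lay within 3 standard errors. For the 6 most abundant members (Fmod, Thbs4, Chad, Comp, Tnmd and Kera; 1270 RPKM for Fmod in old GSH-low) the ratios ran from 3.92 to 5.00 with an SD of 0.13. They were picked after the whole list was tested. For the 9 genes a mixture and a change within the stem cells cannot be told apart. The sort names no tendon marker to remove such cells. Of the 11 genes 8 had at least 1 RPKM in both young libraries and none is in another list. Sort purity and a difference of age or glutathione content within the stem cells stay open, untested.

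MHC class II genes were higher in old GSH-low than in old GSH-high, with all 7 called and a median log2 fold change of 2.16. Macrophages as their source are argued against, since the median of the 10 macrophage markers was 0.07 (SD 0.66). B lymphocytes are a candidate source: the 4 B-lymphocyte genes of the table (of 6 listed) were all higher in both old GSH-low libraries than in both old GSH-high libraries, with Cd79a at 8.60 against 1.68 RPKM and Cd79b at 2.09 against 0.0389. The CD45 gate should remove such cells, and Ptprc, which encodes CD45, averaged 0.574 RPKM in old GSH-low and 0.0815 in old GSH-high; 1 of the 7 lymphocyte list genes in the table had at least 1 RPKM in both young libraries and 1 is in another list. Of the 7 class II genes 5 also rose in old GSH-high against young, where Cd79a averaged 1.68 and 0.695 RPKM and Cd79b 0.0389 and 0.0466, and a difference of age or glutathione content within the stem cells stays open, untested.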

How the results depend on the processing

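Removing a trend over gene length and GC content and setting replaced zeros back to 0 were chosen after the data were seen; the other alternatives were planned. Under the scalings, filters, pseudocount, limma-voom and those added settings, the counts of changed genes ran from 486 to 702 for old GSH-low against old GSH-high, from 3042 to 3486 for old GSH-high against young and from 3746 to 4327 for old GSH-low against young. All genes called both there and in the reported fit had the same direction. With only the 4 libraries of each comparison, 864, 2709 and 3341 genes were called. Median log2 differences between replicates were 0.135 in young, 0.085 in old GSH-high and 0.095 in old GSH-low. The stricter fold change of at least 2 left 173, 432 and 592. Under library size only, the pseudocount of 0.1, no filter and the trend removed, 20 to 21, 22 to 24 and 22 to 23 lists were called, and 2380 to 2778 genes were shared by the age comparisons; 3240 were shared at an adjusted p under 0.1.

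Leaving out each library in turn gave 312 to 863 genes between the old fractions, 1493 to 3802 for old GSH-high against young and 2068 to 4295 for old GSH-low against young. It gave 16 to 27, 22 to 25 and 22 to 25 gene lists, and 1299 to 3015 genes shared by the age comparisons. A library left alone in its group was assumed to vary like the other groups, and fewer samples leave fewer degrees of freedom. Camera with an estimated correlation called 0, 0 and 0 lists, where fry called 9, 22 and 23 and the preset correlation 19, 24 and 23; at an unadjusted p the preset correlation gave 23, 25 and 25. No called list's median changed sign under any setting run.

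The replicate numbers repeat across groups, and the labels do not say that an old GSH-high and an old GSH-low library of 1 number came from the same pool. The differences between replicates correlated over genes at 0.069 between the old fractions, and at -0.142 and -0.263 between young and old libraries, which are from other animals. With the replicate number as a block, 479, 2559 and 3350 genes and 19, 26 and 24 lists were called, and 2053 genes were shared by the age comparisons; with the block in old samples only, 543 genes were called between the fractions.

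The 180 named results, each for 1 gene in 1 comparison, were recomputed under up to 18 settings, 3111 times in all: 2973 kept direction and side of the threshold, 110 lost the call, 15 gained it and 13 changed sign, and 120 results kept both throughout. The sign changes were in 8 results that did not pass the test. With the length and GC trend removed, Gpx1 was -0.036 between the old fractions, Gpx1 0.028 and Gpx4 0.049 in old GSH-high against young, and Vcam1 -0.006 in old GSH-low against young. Leaving out libraries gave, between the old fractions, -0.268 to 0.047 for Gclc, -0.277 to 0.005 for Gsr and -0.041 to 0.084 for Gpx1. It gave -0.266 to 0.037 for Gpx1 and -0.240 to 0.104 for Gpx4 in old GSH-high against young. In old GSH-low against young it gave -0.244 to 0.058 for Gpx1, -0.046 to 0.297 for Gpx4 and -0.010 to 0.102 for Vcam1. The cause was not tested. A DESeq2 Wald test, planned for a file of counts, was not run. Simulated 1.5-fold changes, with 200 genes changed, were recovered for 31.7% to 33.7% on average. The real fit also called smaller ones. Unequal spread may change recovery.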

Other observations

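The tests of gene length and GC content were written before their result was seen, and the removal of that trend was added after the data were seen; the gene lists were fixed beforehand.

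Between the old fractions, some metabolic and growth lists had small shifts. Cholesterol biosynthesis genes had a median log2 fold change of 0.10 in old GSH-low with none of 22 past the test, 0 adjusted over the list alone (camera adjusted p = 0.0410; adjusted p = 0.334 with an estimated correlation). That call ended without old GSH-high replicate 1 (adjusted p = 0.0966) or 2 (0.0785), without old GSH-low replicate 1 (0.216; median 0.049), with a replicate block (0.0531) and with no filter (0.0904), and the median was 0.153 without old GSH-low replicate 2. Methionine, one-carbon and polyamine genes had a median of -0.12 with none of 28 past the test, 0 adjusted over the list alone (camera adjusted p = 0.0433; adjusted p = 0.334 with an estimated correlation). That call ended without young replicate 1 (adjusted p = 0.0551) or 2 (0.0548), old GSH-high replicate 1 (0.129; median -0.075) or old GSH-low replicate 2 (0.125; median -0.077), and with the length and GC trend removed (0.0768). DNA replication genes of S phase fell in 1 of 22, 2 adjusted over the list alone (median -0.15, camera adjusted p = 0.0178; adjusted p = 0.524 with an estimated correlation), a call that ended without old GSH-high replicate 2 (adjusted p = 0.0871). Fatty acid oxidation genes fell in 2 of 23, 2 adjusted over the list alone (median -0.07, camera adjusted p = 0.0383; adjusted p = 0.523 with an estimated correlation), a call that ended without old GSH-high replicate 2 (adjusted p = 0.15; median -0.024) and with the length and GC trend removed (0.0601); the median was -0.117 without old GSH-high replicate 1. One of them was Cd36 (a fatty acid transporter that endothelium also carries), at 3.03 ± 1.57 RPKM (SD, n = 2) against 15.9 ± 1.18, beside the endothelial median of -1.19. Nuclear-encoded oxidative phosphorylation (78 genes, camera adjusted p = 0.237) and ribosomal protein genes (81 genes, 0.949) had no member past the test between the fractions, 0 and 0 adjusted over each list alone. Their medians were -0.131 and -0.088 without old GSH-low replicate 2 and 0.069 and 0.077 without old GSH-low replicate 1. The reported fit had -0.039 and -0.004.

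Of the lists of signalling and stress, the 6 that follow were called in none of the comparisons in the reported fit. TGF-beta signalling genes rose in 2 of 24 between the fractions, in 7 with 2 falls in old GSH-high against young and in 10 with 1 fall in old GSH-low against young; adjusted over the list alone 3, 9 and 10 rose and 0, 3 and 1 fell (camera adjusted p = 0.124, 0.347 and 0.0684). That list was called up between the fractions without old GSH-low replicate 2 (median 0.131, adjusted p = 0.0305). It was called up without young replicate 2 in old GSH-high (0.216, adjusted p = 0.0368) and in old GSH-low against young (0.251, adjusted p = 0.00621), and in the latter also without old GSH-low replicate 2 (0.194, adjusted p = 0.0417). Notch pathway genes rose in 1, 4 and 7 of 18 and fell in 1, 3 and 3; over the list alone 2, 4 and 8 rose and 2, 3 and 3 fell (camera adjusted p = 0.237, 0.570 and 0.209). Targets of p53 rose in 1, 4 and 5 of 29 and fell in 0, 10 and 11; over the list alone 1, 6 and 5 rose and 0, 10 and 12 fell (camera adjusted p = 0.949, 0.209 and 0.195). Genes of the ATF4 stress response, which includes amino acid synthesis and import, rose in 2, 1 and 7 of 34 and fell in 1, 9 and 10; over the list alone 2, 1 and 8 rose and 1, 9 and 10 fell (camera adjusted p = 0.675, 0.423 and 0.412). Iron handling and ferroptosis genes rose in 0, 7 and 8 of 25 and fell in 0, 4 and 8; over the list alone 0, 9 and 9 rose and 0, 6 and 8 fell (camera adjusted p = 0.340, 0.494 and 0.650). Apoptosis regulators rose in 1, 5 and 7 of 27 and fell in 0, 6 and 7; over the list alone 2, 6 and 7 rose and 1, 6 and 7 fell (camera adjusted p = 0.915, 0.690 and 0.650); between the fractions their median of -0.02 was negative where camera pointed up.

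Ribosomal protein and oxidative phosphorylation genes, which are short (median gene lengths of 1770 and 1778.5 bases against 4370 for all genes), were lower in both old groups than in young. Trends over gene length and GC content that differ between libraries are argued against as the whole cause: with the trend removed, the ribosomal protein median kept at least 73.6% of its size (from -0.37 to -0.27 and from -0.37 to -0.28) and 44 and 51 of 81 fell, where 35 and 43 had. The oxidative phosphorylation median kept at least 72.1% (from -0.49 to -0.36 and from -0.50 to -0.39) and 56 and 68 of 78 fell, where 52 and 66 had. What stays open is young replicate 1, without which the ribosomal protein medians were -0.19 and -0.19 with 6 and 16 falls, and the oxidative phosphorylation medians -0.32 and -0.34 with 28 and 43 falls. A difference of age stays open, untested.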
